A study of Mus musculus with 4 samples.

How the data were processed

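The study measured gene expression with Affymetrix mouse arrays in immortalized brown preadipocytes, the precursor cells of brown fat, in which the gene for the histone H3 lysine 9 methyltransferase G9a carried floxed alleles. Vector-treated cells, labelled wild type, were the control group, and Cre-treated cells, labelled G9a knockout, were the other group. Each group held 2 arrays, numbered 1 and 2 in the labels. The labels do not say whether the arrays of a group came from separate cultures, and the sex-linked transcripts given below differ between them, so p-values measure a spread between these arrays that includes a difference in the origin of the cells. The number of arrays limits the precision of every value.

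The authors deposited 1 value per probe set and array, a signal intensity on a linear scale. Per the submitters' processing notes it was made with MAS5, which combines the probe pairs of a probe set into 1 signal. The version and settings are not given in the sources used here. In the deposited values, the mean of each array after trimming 2% from each end was 500, so each array had been scaled to a common target. The table held 45101 probe sets. The 64 Affymetrix control probe sets were kept for quality values only, which left 45037. Of these, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none there. Symbols were updated through the gene ID to RefSeq annotation of GRCm38.p6, where 34741 probe sets matched. That annotation also gave the order of genes along chromosomes, and none of its coordinates are printed.

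Array medians still differed by up to 0.50 on the log2 scale, above the 0.2 at which quantile normalization was to be applied, so the intensities were quantile normalized and the scaling as deposited served as an alternative. That rule did not foresee arrays scaled on their mean, as these were. The choice was made before any group was tested. Values were then taken as log2(signal + 16). All fold changes are on that scale, which understates the change of dim genes. Probe sets with a mean at or above the 50th percentile over all 4 arrays were tested, 22519 in number. A gene was represented by its brightest probe set with 1 symbol, which gave 11079 genes. Differences are knockout minus control, from lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Standard errors (SE) and 95% intervals come from that model, with 2 residual and 4.1 prior degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

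The replicate numbers were checked for pairing. The deviations of same-numbered arrays from their group means correlated at 0.603 across probe sets, which are not independent. Transcripts of the X-linked Xist and of Y-linked genes parted the numbers: a probe set of Xist read 11049 (control) and 9810 (knockout) in number 1 and 41.8 and 58 in number 2, while Eif2s3y read 141 and 228 in number 1 and 1127 and 1265 in number 2. In number 1 the Eif2s3y readings lay above the array medians of 67.2 (control) and 78 (knockout), so a single sex there is not settled. Arrays of 1 number still shared a pattern of sex-linked transcripts and differed in it from the other number. On that ground the numbers were taken to pair the arrays. These transcripts were read after the models with and without the pairing had been fitted. The planned model without the pairing remained the main one. Results of the paired model, with the replicate number as a block, are given where they change a call. That model has 1 residual degree of freedom, with 9.81 prior degrees of freedom.

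Altogether 35 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 34 lists with at least 5 tested members were tested with camera in limma at its preset correlation of 0.01, with adjustment over the lists. The endothelial markers, with 4 tested members, were not tested. An estimated correlation, fry, and 10000 random lists matched on size and mean level were also used. With an estimated correlation camera is limited to the residual degrees of freedom, 2 here and 1 with the pairing. A list could then hardly pass after adjustment, so a failure there says little about it. Named were 11 genes chosen in advance, then the 12 genes that led in each direction. Since no gene passed the adjusted threshold, these were the ones with the smallest p and no overlap of the groups. Up to 4 members of a described list were named, those with the smallest p, and genes outside the rule are said to be chosen after their values were seen.

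Alternatives were pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, the deposited scaling, median centring, eBayes without the trend or in its robust form, the replicate block, and leaving out each array in turn. Leaving out 1 array also unbalances the replicate numbers, so a value that differs between the numbers moves for that reason too. Genes were also represented by the mean of their probe sets or without probe sets that can match several transcripts. Lists were also tested with camera on ranks, and a 1.5-fold limit was set beside the 2-fold one. The procedure was tested on simulated data with 10 runs of 22519 probe sets, 200 of them changed. With a difference between the numbers of the size seen here, the model without the block recovered 1.2% of 2-fold, 35.6% of 4-fold, 85.8% of 8-fold and 99% of 32-fold changes, with 0 false calls. The paired model recovered 64.8%, 99%, 100% and 100%, and 14.8% of its calls were false, above the nominal 5%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.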

Results

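Total RNA of immortalized mouse brown preadipocytes was hybridized to 4 arrays, 2 of vector control cells and 2 of Cre-treated cells in which G9a was knocked out. The study asked how loss of G9a alters gene expression in these cells, and its title names PPARγ and adipogenesis. Array medians were 67.2 and 50.6 signal units in controls 1 and 2 and 78 and 52.5 in knockouts 1 and 2. The ratio of 3′ to 5′ signal of the Gapdh control probe sets lay between 0.794 and 0.866, and that of beta-actin between 1.08 and 1.23. The 2 arrays of each replicate number resembled each other (median absolute log2 differences of 0.24 and 0.21) more than the 2 arrays of each genotype (0.29 in controls and 0.31 in knockouts).

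Ehmt2, the gene that encodes G9a, read 2682 and 2688 signal units in the control arrays and 953 and 912 in the knockout arrays. Its brightest probe set (1460692_at) was 2.81-fold lower in the knockout, a log2 difference of -1.49 ± 0.20 (SE, n = 2 against 2; 95% interval -1.98 to -0.996). The second probe set (1426888_at) differed by -1.39 ± 0.38. Neither passed the threshold over all probe sets without the pairing (limma adjusted p = 0.227 and 0.779). In the paired model Ehmt2 fell, with a limma adjusted p of 0.000281 and differences of -1.50 and -1.48 within pairs 1 and 2. The labels do not name the deleted exons, so a probe set outside them would check nothing. Ehmt1, which encodes the G9a partner GLP, differed by -0.33 ± 0.22 (adjusted p = 0.999).

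Pparg, the nuclear receptor that drives adipogenesis, did not differ detectably between the genotypes. Its signal was 111 and 252 in the controls and 132 and 349 in the knockouts, a log2 difference of 0.26 ± 0.64 (95% interval -1.30 to 1.82; limma adjusted p = 0.999, and 0.612 in the paired model). The pairs gave 0.13 and 0.39, while array 2 exceeded array 1 by 1.33 in the controls and by 1.59 in the knockouts. The SE of 0.64 counts that difference between the replicate numbers as spread. With the pairing, which leaves 1 residual degree of freedom, the SE was 0.22. Leaving out 1 array unbalances the replicate numbers and thereby moved the difference, to -0.41 without control 1 and -0.53 without knockout 2. The adipogenic C/EBP factors lay lower without passing over all genes in either model: Cebpa by -0.49 ± 0.41, Cebpb by -0.45 ± 0.43 and Cebpd by -0.46 ± 0.58. Each was lower in both pairs, Cebpa by -0.23 and -0.76, Cebpb by -0.498 and -0.40 and Cebpd by -0.60 and -0.33. The SEs in the paired model were 0.27 for Cebpa, 0.11 for Cebpb and 0.14 for Cebpd. Adjusted over the list of adipogenic transcription factors alone, Cebpb and Cebpd fell in the paired model (limma adjusted p = 0.0181 and 0.0209). Cebpa did not pass there (limma adjusted p = 0.222). Array 2 lay below array 1 by 0.46 to 1.47 in the controls and by 0.95 to 1.21 in the knockouts. With the numbers unbalanced, Cebpa was -0.26, Cebpb 0.08 and Cebpd 0.27 without control 1, and -0.0031, 0.03 and 0.14 without knockout 2. They were -1.01, -0.93 and -1.08 without knockout 1, and -0.71, -0.97 and -1.19 without control 2.

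Fabp4, the fatty acid binding protein of adipocytes and a target of PPARγ, was 6.27-fold higher in the knockout, with 186 and 112 signal units in the controls and 908 and 1120 in the knockouts (log2 difference 2.65 ± 0.27). Its limma adjusted p was 0.145, and 0.000104 in the paired model, in which it rose. A second probe set differed by 2.02 ± 0.40. Wnt10a, which encodes a Wnt ligand that restrains adipogenesis, was 3.72-fold lower (-1.89 ± 0.35; adjusted p = 0.409, and 0.00405 in the paired model, in which it fell). Wnt10b differed by -0.65 ± 0.50 and did not pass. Prdm16, a regulator of brown fat identity, was 0.89 ± 0.30 higher with an adjusted p of 0.999 (0.11 in the paired model), and its 3 other probe sets, all below the level filter, differed by -0.03, -0.10 and 0.20. Ucp1, the uncoupling protein of mature brown fat, lay below the filter, with signals of 8.7 and 6 in the controls and 10.1 and 21.8 in the knockouts.

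**Figure D1:**
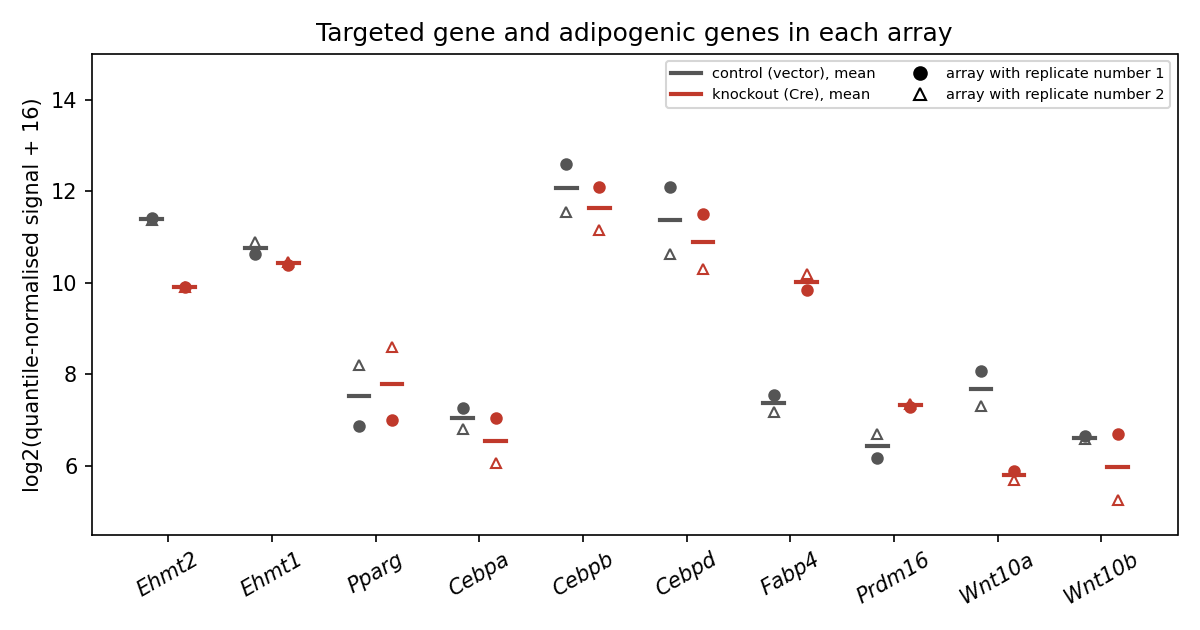
Normalized log2(signal + 16) of 10 genes in each of the 4 arrays, with control and knockout arrays in separate columns, circles for replicate number 1 and triangles for number 2. Ehmt2 and Wnt10a lie lower and Fabp4 higher in both knockout arrays, while the Pparg values part by replicate number, from 6.87 and 7.01 in number 1 to 8.21 and 8.60 in number 2.

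Tnn, which encodes the matrix protein tenascin-N, was 15.2-fold higher (log2 difference 3.92 ± 0.32), with 4.5 and 6.6 signal units in the controls and 418 and 247 in the knockouts. Ifi27l2a, an interferon-inducible gene, was 11.5-fold higher, the aldo-keto reductase gene Akr1c13 was 11-fold higher and the mast cell tryptase gene Tpsab1 was 10.3-fold higher. Ces1g, a carboxylesterase gene, was 8.21-fold higher. Gabra4, a GABA receptor subunit gene, was 7.26-fold higher, Kcnmb1, which encodes a subunit of the calcium-activated potassium channel of smooth muscle, 7.19-fold, and Mndal, of the interferon-inducible p200 family, 6.98-fold. Where the controls are dim the pseudocount sets much of the fold: at 64 in place of 16 the log2 differences were 2.46 for Tnn, 2.16 for Ifi27l2a and 2.28 for Akr1c13, below the 2.59 of Col18a1. Brighter in control cells were Col18a1, the collagen XVIII gene, which was 6.40-fold higher with 774.5 and 559 units in the controls and 4693 and 3922 in the knockouts, Gpx3, an extracellular glutathione peroxidase gene, at 5.99-fold, and Nrep at 3.27-fold. These 11 genes and Fabp4 had limma adjusted p-values from 0.0967 (Tnn) to 0.175 (Gabra4), so none passed without the pairing. All 12 rose in the paired model, with adjusted p-values from 4.58e-06 (Col18a1) to 0.000708 (Kcnmb1).

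Among lower genes, the uncharacterized gene 2610316D01Rik was 8.21-fold lower (-3.04 ± 0.29), though its second, dim probe set differed by 0.29. Gap43, which encodes a growth cone protein, was 7.999-fold lower, with 1142 and 643 signal units in the controls and 84.6 and 113 in the knockouts. Igfbp6, a binding protein for insulin-like growth factors, was 4.04-fold lower, and Ptx3, a secreted pentraxin gene, 4.02-fold lower. The extracellular matrix gene Svep1 was 3.76-fold lower, Msi1, an RNA-binding protein gene, 3.31-fold, Pdzrn3 2.82-fold, Slc16a11 2.46-fold, Syce2 2.15-fold and the BMP antagonist gene Grem1 1.99-fold. With Ehmt2 and Wnt10a, these were the 12 lower genes with the smallest p. Their limma adjusted p-values ran from 0.111 to 0.486 without the pairing. All 12 fell in the paired model, with adjusted p-values from 0.000112 (Igfbp6) to 0.00933 (Slc16a11). The 12 genes in each direction were picked by their p on the same 4 arrays, so their passing there is no independent check.

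Among large differences, more genes were higher than lower in the knockout, while the median log2 difference over all genes was 0.007. With a mean difference of at least 2-fold and no overlap of the groups, 336 probe sets were higher and 115 were lower, so 74.5% were higher, and at gene level 242 were higher and 63 lower. Before any fold limit, 30% of probe sets were parted without overlap by genotype, 53% by replicate number and 17% when the arrays were crossed. With 2 arrays against 2, chance alone would part 33.3%. Barring ties, each probe set is parted in exactly 1 of these 3 ways. The large share by replicate number therefore lowers the shares by genotype and when crossed, and the counts drawn from them. The 2-fold rule gave 39 probe sets when the arrays were crossed, and 816 between the replicate numbers. In both pairs alike, 226 probe sets were at least 2-fold higher in the knockout and 56 at least 2-fold lower, against 5 that were 2-fold apart in opposite directions. At 1.5-fold, 1414 probe sets passed and 58.6% were higher. At 2-fold, the 451 probe sets became 898 without the filter (65.8% higher), 118 with the 75th percentile filter (71.2%) and 277 with a pseudocount of 64 (78.7%). With 1 array left out, which makes non-overlap easier to meet, they were 1005 without control 1 (68.2% higher), 1156 without knockout 2 (60.4%), 646 without knockout 1 (57.3%) and 645 without control 2 (61.2%).

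Without the pairing, 2 probe sets rose at a limma adjusted p under 0.05 and 0 fell. Both are without a gene name here: 1415848_at was 30-fold higher (4.91 ± 0.27; adjusted p = 0.0208) and 1439002_s_at 82.1-fold higher (6.36 ± 0.36; adjusted p = 0.0208). No named gene passed, 0 in either direction, and 562 genes had an unadjusted p under 0.05 (421 higher and 141 lower), or 2036 with the replicate number as a block, where chance would give 554. Without the intensity trend, limma called 0 probe sets. With the replicate number as a block, 516 probe sets rose and 192 fell, or 360 and 109 genes. In simulated data with 200 changed probe sets, 14.8% of that model's calls were false. That share depends on how many probe sets are changed, so it need not be the share here. Single genes near the threshold are less certain than the adjusted p states.

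Interferon-stimulated genes, which cells turn on in response to interferon, were higher as a group. All 31 tested members had a positive difference. Of these, 26 were higher in both knockout arrays than in both controls, where chance would give 16.7% of members. Their median log2 difference was 1.08, above 100% of the random lists. Rtp4 was 3.53-fold higher (1.82 ± 0.26), Xaf1 4.77-fold (2.25 ± 0.32), and Ifit1, which encodes a protein that binds viral RNA, 2.68-fold (1.42 ± 0.24), beside Ifi27l2a. Adjusted over the list alone 22 members rose, and over all genes 0 did. Under the pairing 19 rose over all genes, 27 adjusted over the list alone, and the list's medians within pairs 1 and 2 were 1.31 and 1.01. The list passed camera (adjusted p = 4.13e-27), but not with an estimated correlation (adjusted p = 0.473). Macrophage and leukocyte markers, 7 of them tested, had a median of 0.25 (camera adjusted p = 0.359).

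Antigen presentation genes, which load peptides onto MHC class I molecules, were higher as well (15 members, all positive, median 0.41; camera adjusted p = 6.62e-07, and adjusted p = 0.473 with an estimated correlation). Psmb8, an immunoproteasome subunit gene, was 3.47-fold higher (1.79 ± 0.35), and the MHC class I genes H2-D1 and H2-M3 were 2.81-fold and 1.92-fold higher. Nlrc5, the transactivator of MHC class I genes, was 2.17-fold higher. Adjusted over the list alone 3 members rose, and 0 did over all genes. The paired model gave 5 that rose over all genes and 7 adjusted over the list alone. Psmb8, Psmb9 and Tap1 are also members of the interferon list. The list's median was 0.25 without knockout 1 and 0.22 with the 75th percentile filter.

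Contractile genes were higher. The smooth muscle and myofibroblast markers had a median of 0.39 over 13 members, 12 of them positive (camera adjusted p = 0.00124, and adjusted p = 0.763 with an estimated correlation). Myl9, a myosin light chain gene, was 1.73-fold higher (0.79 ± 0.15), Cnn1, which encodes calponin, 1.98-fold, Mylk, the myosin light chain kinase gene, 2.39-fold, and Actg2, the enteric smooth muscle actin gene, 2.75-fold. Of the members, 1 (Myl9) rose adjusted over the list alone, and 0 rose over all genes, against 6 and 3 in the paired model. The muscle markers had a median of 0.59 over 10 members, 8 of them positive (camera adjusted p = 0.00124, and adjusted p = 0.568 with an estimated correlation). Tnnt2, the cardiac troponin T gene, was 3.35-fold higher (1.75 ± 0.37) and the skeletal actin gene Acta1 2.44-fold (1.29 ± 0.24). These 2 rose adjusted over the list alone, and in the paired model also over all genes. Myl4 and Des were 1.64-fold and 1.73-fold higher and did not pass in either model over all genes. The smooth muscle median ran from 0.16 without knockout 1 to 0.72 without knockout 2, and was 0.12 with the 75th percentile filter, 0.24 with median centring and 0.66 without probe sets that can match several transcripts. The muscle list was no longer called without the level filter (median 0.24; adjusted p = 0.0705), and the 75th percentile filter left too few members to test it.

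The extracellular matrix list was called higher by a smaller margin, with a median of 0.14 over 37 members, 28 of them positive (camera adjusted p = 0.00926, and adjusted p = 0.875 with an estimated correlation). Col18a1 and Col15a1, the genes of 2 basement membrane collagens, were 6.40-fold and 3.08-fold higher and rose adjusted over the list alone, and 0 members passed over all genes. Fbln1, the fibulin 1 gene, was 1.92-fold lower and Col8a1 1.60-fold higher. In the paired model 8 members rose and 4 fell over all genes. Among the 4 was Dcn, named after its value was seen, with differences of -1.85 and -2.17 within pairs 1 and 2. The list's call was lost with median centring (median 0.098) and without the trend, where the median stayed at 0.14. It was also lost without knockout 1 (0.07) and without control 2 (0.09). The median was 0.39 without control 1, 0.25 without knockout 2 and 0.21 without the level filter.

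Genes of cholesterol biosynthesis and of the cell cycle were lower by small amounts. The cholesterol list had a median of -0.20 over 21 members, 15 of them negative (camera adjusted p = 0.00538, and adjusted p = 0.568 with an estimated correlation). Its leading members were Sqle, the squalene epoxidase gene (-0.39 ± 0.18), Srebf2, the gene of the transcription factor that controls the pathway (-0.56 ± 0.26), Hmgcs1 (-0.24 ± 0.13) and Lss (-0.43 ± 0.23). The cell cycle list had a median of -0.15 over 40 members, 30 of them negative (camera adjusted p = 0.00538, and adjusted p = 0.875 with an estimated correlation), led by the transcription factor gene E2f2 (-0.82 ± 0.32), the ribonucleotide reductase gene Rrm1 (-0.32 ± 0.15), Cdc6 (-0.40 ± 0.27) and the topoisomerase gene Top2a (-0.21 ± 0.14). In both lists 0 members passed over all genes or adjusted over the list alone, in either model. The cholesterol call was lost without control 1 (median -0.13) and without knockout 2 (-0.23), and the cell cycle call without control 1 (-0.16) and without knockout 1 (-0.04). With median centring the medians were -0.32 and -0.26. The cholesterol list had medians of -0.18 and -0.11 within pairs 1 and 2. For the cell cycle list they were -0.20 and -0.06, with 7 and 15 of the 40 members positive.

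With all 4 arrays and the planned settings, the lists closest to the study's title did not pass camera without the pairing. Adipogenic transcription factors had a median of -0.03 over 23 members (adjusted p = 0.121). Zfp521, a repressor of adipocyte commitment, was 1.88-fold lower, Ebf3 1.56-fold, Klf5 1.503-fold and the orphan receptor gene Nr4a1 1.69-fold. With a repressor among its members, the direction of the list does not by itself give that of adipogenesis. In the paired model the list passed as lower (camera adjusted p = 0.0439, and adjusted p = 0.874 with an estimated correlation), and 2 of its members, Zfp521 and Nr4a1, fell over all genes, with 1 rising and 7 falling adjusted over the list alone. It also passed as lower with median centring (median -0.16; adjusted p = 0.0442), without knockout 1 (-0.39; 0.000176) and without control 2 (-0.25; 0.000145), while its median was 0.08 without control 1 and 0.03 without knockout 2. Its medians within pairs 1 and 2 were -0.12 and -0.24, and the list itself differed between the replicate numbers. Mature adipocyte and PPARγ target genes had a median of -0.10 and a mean of 0.10 over 22 members (camera adjusted p = 0.99, direction up). Beside Fabp4, the pyruvate dehydrogenase kinase gene Pdk4 was 1.99-fold higher and rose in the paired model (adjusted p = 0.0162). That model also called 1 member lower over all genes, Angptl4 (adjusted p = 0.0353), named after its value was seen. Plin4 and Plin2, genes of lipid droplet proteins, were 1.73-fold and 1.27-fold higher and did not pass in either model over all genes. Brown fat genes had a median of 0.11 and a mean of -0.02 over 10 members (camera adjusted p = 0.956, direction down). Led by Prdm16, its other leading members were Elovl6 (-0.43 ± 0.23), Ppargc1b (-0.82 ± 0.46) and Dio2 (0.60 ± 0.39), and 0 members passed over all genes in either model.

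Wnt ligands, receptors and antagonists had a median of -0.06 over 22 members, 11 positive and 11 negative (camera adjusted p = 0.618). Wnt10a fell adjusted over the list alone, and it was the sole member to pass over all genes in the paired model. Rspo2, which encodes an enhancer of Wnt signalling, was 1.81-fold lower, and Wnt5a and Wnt9a were 1.58-fold and 1.48-fold higher, none of them passing over all genes. The H3K9 methylation and demethylation machinery had a median of -0.12 over 30 members (camera adjusted p = 0.0795), and passed as lower with the 75th percentile filter (median -0.22; adjusted p = 0.0116). Beside Ehmt2, Mecom, also known as Evi1, was 1.83-fold higher and rose in the paired model (adjusted p = 0.017), while the demethylase genes Kdm7a (0.76 ± 0.35) and Kdm4b (-0.48 ± 0.25) did not pass.

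Targets of p53 had a median of 0.13 over 25 members (camera adjusted p = 0.0907 without the pairing). The list passed as higher in the paired model (camera adjusted p = 0.00992, and adjusted p = 0.874 with an estimated correlation), where 6 members rose over all genes and 9 adjusted over the list alone. Without the pairing it passed without control 1 (median 0.42; adjusted p = 0.00238) and without knockout 2 (0.35; 0.00504), and not without knockout 1 (0.06) or control 2 (0.04). It also passed with the 75th percentile filter (0.28; 0.00754), with mean probe sets (0.16; 0.0152), with median centring (0.02; 0.0442) and without probe sets that can match several transcripts (0.16; 0.0497). Trp53inp1 was 2.30-fold higher and the cell cycle inhibitor gene Cdkn1a 1.499-fold, and both rose in that model (adjusted p = 0.00757 and 0.032). Eda2r (1.55-fold) did not pass, and Ephx1, an epoxide hydrolase gene, rose by 1.95-fold (adjusted p = 0.00577). Preadipocyte and fibroblast markers (median 0.31 over 16 members) and immediate early genes (median -0.17 over 32 members) likewise passed in the paired model and not in the planned one, with camera adjusted p-values of 0.0231 (higher) and 0.0439 (lower), against 0.291 and 0.134 without the pairing and 0.874 for both with an estimated correlation. Of these, the fibroblast markers passed without control 1 (median 0.46; adjusted p = 0.0324), and their median was -0.01 without knockout 1 and 0.06 without control 2. The immediate early genes passed without knockout 1 (-0.39; 7.84e-07) and without control 2 (-0.34; 0.000351), and had medians of 0.01 without control 1 and 0.11 without knockout 2. Within pairs 1 and 2 the medians were 0.19 and 0.16 for the p53 targets, 0.27 and 0.39 for the fibroblast markers and -0.10 and -0.22 for the immediate early genes. With an estimated correlation 0 of the 34 lists passed in either model, where few degrees of freedom are left. Calls were lost there also where the estimated correlation lay below the preset 0.01, as for antigen presentation (-0.021), muscle (-0.1075) and cholesterol (-0.0478). The fry test without the pairing gave 1 list an adjusted p under 0.05, the muscle markers (0.000319). In all, 7 lists passed camera without the pairing and 11 with it.

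**Figure D2:**
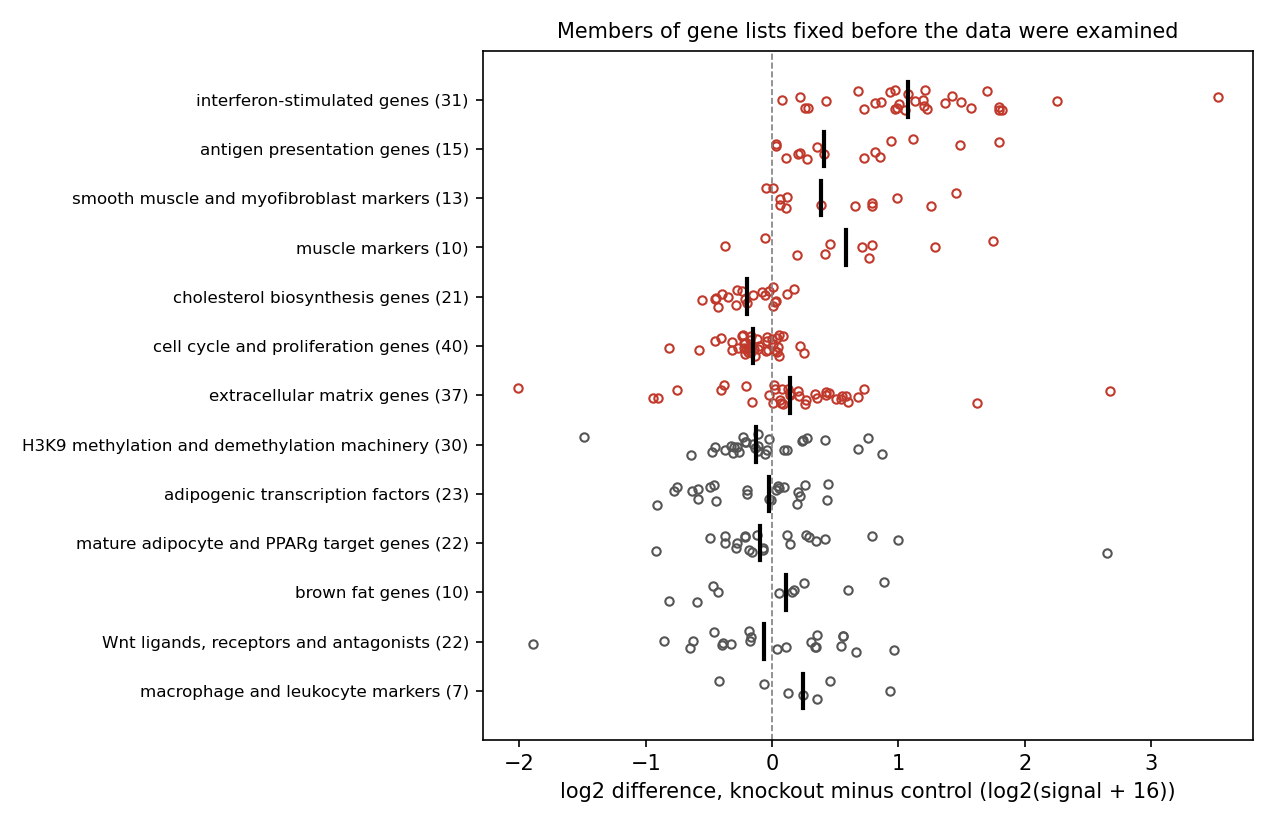
Log2 difference, knockout minus control, of each tested member of 13 gene lists, 1 point per gene, with the median of each list marked and lists with a camera adjusted p under 0.05 in red. The interferon-stimulated genes have the highest median, 1.08, and all 31 of their points lie above 0.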

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

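No test in this part was chosen in advance, since the pairs were compared only after the values had been seen. The Wnt ligand gene Wnt10b had differences of opposite sign in the pairs. The log2 difference was 0.037 between knockout 1 and control 1 and -1.33 between knockout 2 and control 2. The value in pair 1 is below the median absolute log2 difference of those 2 arrays (0.24), so it shows no clear movement. The signal in knockout 2 was dim (18.7). The difference between the pairs was not tested, as each holds 1 array per genotype.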

How the results depend on the processing

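All alternatives here were planned. In the paired model, with the replicate number as a block, 516 probe sets and 360 genes were higher, 192 and 109 were lower, 11 lists passed, and Ehmt2 passed (-1.49; adjusted p = 0.000281, against 0.227). Ehmt2 kept its direction under every alternative, with adjusted p-values from 0.201 to 0.62 in the rest, and the block turned the direction of no list called without it. Probe sets called higher numbered 1 with a pseudocount of 1 and with the 75th percentile filter, and 0 without the filter or without the trend. Median centring, which moved the median of all probe sets to -0.11, called 14 probe sets and 9 genes higher and 2 and 2 lower. The count at 2-fold without overlap was 1414 at 1.5-fold, 277 with a pseudocount of 64, 898 without the filter and 118 with the 75th percentile filter. Leaving out 1 array leaves an arm with 1 sample, assumed to vary like the other group, and unbalances the replicate numbers. Probe sets called then ranged from 5 (without knockout 1) to 28 (without control 1) higher and from 0 to 2 lower, genes from 3 to 18 higher and from 0 to 1 lower, lists from 7 to 11, and the 2-fold count from 645 (without control 2) to 1156 (without knockout 2), 57.3% to 68.2% of it higher. Pparg ranged from -0.53 (without knockout 2; -0.41 without control 1) to 1.08 (without knockout 1). Cebpa ranged from -1.01 (without knockout 1) to -0.0031 (without knockout 2), Cebpb from -0.97 to 0.077 and Cebpd from -1.19 to 0.27, lowest without control 2 and highest without control 1, and Wnt10b was 0.074 without knockout 2. Camera reversed for lists that passed nowhere: brown fat genes (medians 0.10 without the filter, 0.047 with median centring, 0.11 with mean probe sets), mature adipocyte genes (-0.16 with the stricter filter, -0.10 in the paired model and on ranks, -0.13 with mean probe sets) and Wnt genes (-0.16 with the stricter filter). With 1 array left out their medians ran from -0.37 to 0.38, from -0.084 to 0.0083 and from -0.13 to 0.18. With 1 array left out, immediate early genes ran from -0.39 to 0.11, macrophage markers from -0.0064 to 0.39 and imprinted genes from -0.032 to 0.11, and imprinted genes were at 0.036 with the stricter filter. With an estimated correlation, which limits camera to the 2 residual degrees of freedom (1 with the pairing), 0 lists passed. A value that differs between the replicate numbers moves when 1 array is left out, and other causes of the moves were not tested. For single genes and lists, 572 values stayed on their side of the threshold, 70 newly passed, 16 no longer passed and 24 reversed. Signal near background limits the dim genes, since the pseudocount then sets their fold.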

Other observations

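Tests chosen only after the result was seen were those of RNA degradation and growth state, of leukocytes and Cre delivery, of related gene families, and of the genes named in the opening paragraphs. Between the replicate numbers, the brown fat list did not pass camera (adjusted p = 0.085), and the genes named next were picked after their values were seen. Zic1 and Lhx8, transcription factor genes expressed in classical brown fat, were higher in number 2 by 3.94 and 4.35 on the log2 scale in the controls and by 4.74 and 3.80 in the knockouts. Ebf2, a selector of brown preadipocytes, was higher by 1.67 and 1.40. The lists with the smallest p between the numbers were the immediate early genes (median -0.51; camera adjusted p = 0.000204) and the NRF2 targets (median 0.42; adjusted p = 0.000317). The adipogenic transcription factors as a list were also lower in number 2 (median -0.45; camera adjusted p = 0.00312), and so were the chemokines and inflammatory genes (median -0.75; adjusted p = 0.00588) and the extracellular matrix genes (-0.23; 0.00871).

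Among the 29 tested imprinted genes, the list as a whole did not pass (camera adjusted p = 0.661; 0.0116 as lower without control 2), but 3 noncoding RNAs of 1 imprinted cluster, Meg3, Rian and Mirg, were 2.36-fold, 2.48-fold and 2.18-fold lower in the knockout. With the pairing Meg3 and Mirg fell (limma adjusted p = 0.0051 and 0.0188) and Rian did not pass (0.0765), its difference lying mostly in pair 1 (-2.26 against -0.36). Dlk1 of the same cluster differed by -0.92 ± 0.44, also mostly in pair 1 (-1.72 against -0.11). The matrix gene Dcn fell 4.02-fold there (adjusted p = 0.00256), while Ndn and Sgce rose (0.0156 and 0.0434). The list of growth factor ligands and receptors did not pass in the paired model (camera adjusted p = 0.226). Of its 32 members 4 rose and 4 fell over all genes, and 24 did not pass. Named after their values were seen, Pdgfa and Pdgfb rose in that model by 1.87-fold and 2.87-fold. Fgf7 and the receptor substrate gene Irs1 fell by 2.17-fold and 1.62-fold. The gene with the smallest p in that model was Prl, the prolactin gene (31.7-fold higher; adjusted p = 3.56e-06), which had an adjusted p of 0.18 without the pairing.

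Arrays of 1 replicate number resembled each other more than arrays of 1 genotype. Dim signal is argued against as the whole cause, since 289 probe sets with a mean above the 75th percentile were 2-fold apart between the numbers, against 6 in the crossed split. The count of 6 is itself lowered by the large share parted by number. RNA degradation is argued against by 3′ to 5′ control ratios that differed at most 1.13-fold, although the 18S rRNA signal was lower in number 2 (4606 and 2512 in control and knockout, against 6345.5 and 5954). Cells of different animals behind the numbers are a possible cause. Of 12 probe sets of Xist and Y-linked genes, 5 were over 4-fold apart in both genotypes, which a growth state would not give. A single sex in number 1 is not settled, so different animals remain an inference. For the other genes a different growth state cannot be told apart from different animals. Of 34 lists, 5 differed between the numbers, and each number holds 1 array per genotype.

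The median rise of interferon-stimulated genes was 1.08 without probe sets that can match several transcripts, and at least 0.97 with the deposited scaling and with median centring, which argues against probe sets with several matches and against scaling. Leukocytes in the knockout cultures cannot be told apart from loss of G9a, since only 7 of the 25 markers with a probe set passed the level filter and the markers went both ways. The 7 had a median of 0.25, with Cd53 rising in the paired model (0.93; adjusted p = 0.0451) and Coro1a at -0.42, the 25 had a median of 0.12 (95% bootstrap interval -0.06 to 0.25, against 0.97 to 1.23 for the interferon-stimulated genes), with Ptprc at -0.52 near background, and the mast cell tryptase gene Tpsab1 was 10.3-fold higher. An effect of Cre or its delivery cannot be told apart from loss of G9a, since they come together in both knockout arrays, and p53 targets had an adjusted p of 0.091, which the paired model lowered to 0.00992 (adjusted p = 0.874 with an estimated correlation). Loss of G9a stays open as a hypothesis, since Cre in cells without floxed alleles was not analysed here.

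Genes at least 2-fold higher in the knockout lay next to each other on chromosomes more often than chance. Of 241 such genes with a position, 26 neighbouring pairs were found where 5.19 were expected (one-sided permutation p = 1e-04, the smallest the permutations can give). Without pairs that share the first 3 letters of their symbols, 15 were left against 5.02 (permutation p = 2e-04), and against 4.92 with genes matched on level (permutation p = 2e-04), which argues against shared probe sequence or low level as the whole cause. Taking out 5 more pairs of related families under other names left 10 pairs (permutation p = 0.03). The 63 lower genes gave 2 pairs against 0.35 (permutation p = 0.05), both among Meg3, Rian and Mirg of 1 imprinted cluster. Genes higher in number 1 than in number 2 gave 10 pairs against 4.82 (permutation p = 0.02), and genes higher in number 2 gave 4 against 2.23 (permutation p = 0.2), so the excess without families is modest and may not be particular to the knockout. Shared chromatin domains of neighbouring genes, as for Fabp7 and Smpdl3a, Nrp2 and Pard3b, or Stmn2 and Hey1, remain a possible explanation.

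Of the 242 genes at least 2-fold higher, 188 (77.7%) had a control mean below the 25th percentile of tested genes, against 44 of 63 lower genes (69.8%) by their knockout mean, a difference Fisher's exact test did not resolve (two-sided p = 0.25).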
